A study of Homo sapiens with 6 samples.

How the data were processed

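Per the labels' protocols, total RNA was extracted with RNeasy kits from HEK293 cells grown in DMEM with 10% fetal bovine serum, and libraries were made with the NEBNext Ultra RNA kit and random primers. Whether poly(A) RNA was selected or ribosomal RNA was depleted was not given in the sources used here. Per the submitters' processing notes, the reads went through bcl2fastq, STAR and Partek with the genome build hg38. Versions, parameters, transcript annotation and filters were not given in the sources used here.

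The authors' deposited table compared mutant with parental libraries for 203376 transcripts. Per the file headers, the authors made the score called LSMean as a least-squares mean for each group, and the values showed it to be the arithmetic mean over a group of a length-scaled abundance plus 1. With 1 taken off, the means summed to 496162.2 in both groups, as a scaling of every library to a common total gives, and this total was not explained in the sources used here. The deposited signal called total counts was not a whole number, and it equalled 3 times the sum of the group means. The deposited ratio was the quotient of the group means, and the deposited fold change, a score with a sign, was that ratio or minus its inverse. The deposited p-value and its adjusted form, also held as scores, were the authors' own, and Benjamini-Hochberg adjustment over 140552 transcripts gave the adjusted form again. A further p-value for the factor named Type stood for 150084 transcripts.

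How the deposited p-value was made was read from the values. The size of 1 read in each library was found from repeated steps in abundance times length, and 1289 transcripts could be turned back into whole reads. For 94.9% of them an equal-variance comparison of log values with 4 degrees of freedom gave the deposited p-value within 0.002, against 45.1% for untransformed values. A p-value of 0.374, held by 19269 transcripts, is what reads in 1 library of 6 give, so a change in 1 library alone cannot give a small p-value. The number of reads in each library was estimated from the same steps.

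Transcript names were matched to GENCODE release 29, where 98.98% of them were found, and gene positions, GC content and length were taken from it on the same build. Abundance was the group mean minus 1, gene abundance was the sum over transcripts, and the log2 ratio was taken after 1 was added to both groups. Genes with an abundance of at least 1 in either group were kept. GC content was known for 99.1% of them.

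The design, the gene lists, the naming rule and 10 of the 15 alternatives run were chosen before the data were examined. The design named fits of single libraries, and where only a comparison by the authors was given it named a description of the authors' values without a test of its own. The second case held, since the values given were group means, so the deposited adjusted p-value at 0.05 made the calls. A list test was added after the files were seen. It was cameraPR of limma 3.58.1 in R 4.3.3, without ranks, with an inter-gene correlation of 0.01, on a signed z from the deposited p-value of the most abundant transcript of each gene. Of 35 lists 32 had at least 5 measured genes and were tested, with Benjamini-Hochberg adjustment over them. Each list was also set against 10000 random lists matched on abundance. Calls over a list alone were adjusted over its measured members.

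Transcripts were named when the adjusted p-value was under 0.05 and the group mean in the higher group was above 1.2, the median of the tested transcripts, at most 10 in each direction. The part of the rule that asks for no overlap of single libraries was not applied. From called or planned lists the 4 members with the smallest p-values were named, and other members, some large gene changes and the zinc finger examples were picked after values had been seen. The large changes were picked at an abundance of at least 5, with most antisense, clone-named and intergenic RNA genes left out by name.

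Alternatives were an abundance of at least 5, no filter on low values, an added 0.1 in place of 1, an adjusted p under 0.01, an absolute log2 ratio of at least 1, and transcript level in place of gene level for the lists or the reverse for the calls. After the files were seen 5 were added: an inter-gene correlation of 0.05, the log2 ratio as the statistic, the removal of GC and length trends by running medians over 40 bins, averaged over 5, and for the calls the adjusted p-value of the factor Type and the removal of called transcripts with 6 whole reads. A replicate block, leaving out single libraries, other normalizations, other test tools, an estimated inter-gene correlation and a rotation test of the lists were planned and could not be run on group means.

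The list test was tested on simulated data with 14856 genes. Their values were drawn independently of each other, so the simulation cannot show how the test behaves when genes are correlated. Of 100 lists of 20 genes without a shift 3 had a p under 0.05 and 0 an adjusted p under 0.05; with a shift of 1 in z 5 of 5 lists were called, and with 0.5 it was 0 of 5. Trend removal returned -0.47 of a planted -0.50. The reading of read sizes was tested on simulated data with 60000 transcripts, where 6 of 6 sizes were found and 2298 of 2298 transcripts were turned into the right reads. Intervals came from 2000 bootstrap draws over genes, and permutation p-values from 100000 draws. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.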

Results

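RNA was sequenced from HEK293 cells, a human embryonic kidney line that is grown to make recombinant protein, here carrying a luciferase reporter. Of the 6 libraries, 3 came from the parental line and 3 from cells labelled as deleted for CASP8AP2 with CRISPR. CASP8AP2, also called FLASH, takes part in the 3' end processing of replication-dependent histone pre-mRNA and was first described as a partner of caspase 8. The question was which transcripts and gene groups differed between the libraries labelled mutant and the parental ones, in a study concerned with protein yield and arrest of the cell cycle at G0/G1. Levels were given as group means of a length-scaled abundance for 203376 transcripts of 56794 named genes, and 140552 transcripts carried a p-value in the authors' deposited table. Abundance is printed below with the authors' added 1 taken off, gene levels are sums over transcripts, and log2 values are ratios of mutant over parental after 1 was added to both. Gene groups were read from 14856 genes with an abundance of at least 1 in either group. Where a gene sum stands beside a p-value or a call over a list alone, that p-value is of the gene's most abundant transcript.

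Depth differed between the libraries. The smallest steps between transcript values gave an estimated 57440000, 15000000 and 13280000 reads on transcripts in the mutant libraries, and 15290000, 11590000 and 9180000 in the parental ones. The deepest mutant library was 6.26 times the shallowest parental one, and its replicate number was not known. Transcripts above 0 in the mutant group alone numbered 16178, against 6318 in the parental group alone. Beyond these read sizes and the whole reads decoded for 1289 transcripts, only group means were analysed, so no spread or error between replicates is given. Nothing in the labels says that replicates were separate cultures, and the deposited p-values then measure only the spread between samples, which may be technical.

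Genes rich in G and C lay higher in the mutant libraries and genes poor in them lower. Across 20 bins of GC content the median log2 ratio ran from -0.15 in the bin up to 37.6% GC to 0.25 in the bin from 64.0% GC. Spearman's rho with GC content was 0.31 across 14723 genes, and with transcript length it was 0.03. The median over all genes was -0.01, with 49.4% of genes higher in the mutant group.

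**Figure D1:**
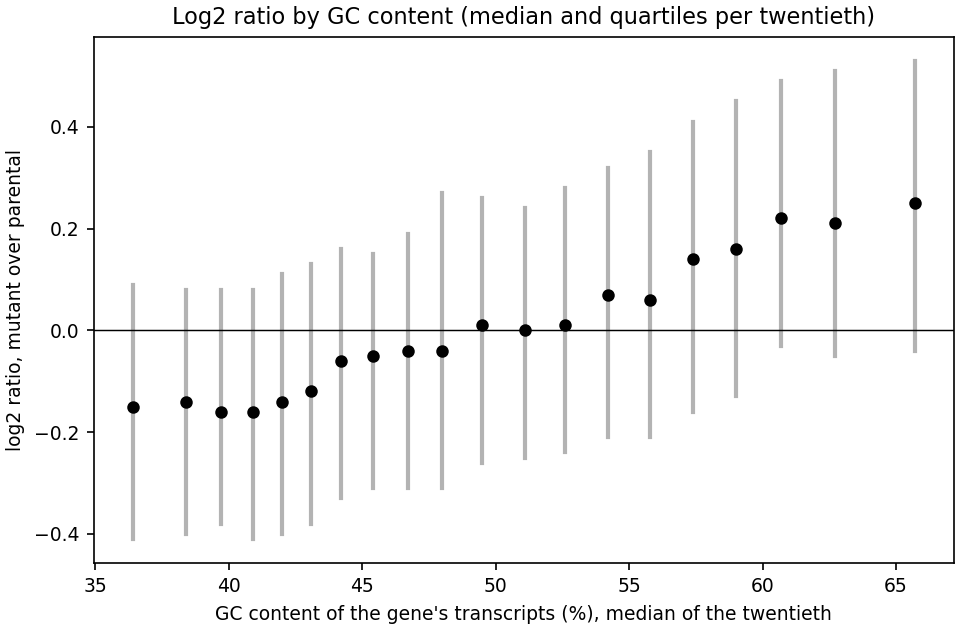
Log2 ratio of mutant over parental against the GC content of each gene, in 20 bins. The medians ran from -0.15 to 0.25, with a rho of 0.31 across 14723 genes.

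CASP8AP2 RNA differed little between the groups. Summed over its 6 transcripts on the plus strand of chromosome 6 (89829894 to 89874436, build hg38), it stood at 15.7 in the mutant and 15.9 in the parental libraries, a log2 ratio of -0.01. CASP8AP2-201 had 6.13 against 6.98, and the protein-coding CASP8AP2-205 had 6.23 against 6.58. None of the 6 transcripts was called in the authors' deposited table, where their p-values lay between 0.142 and 0.976. The list of CASP8AP2 itself and genes around it, such as ANKRD6 and BACH2, had 11 measured members with a median log2 ratio of 0.03 (cameraPR, adjusted p 0.552). The place of the deletion was not given in the sources used here, so the RNA level does not check which cells carried it.

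The clearest transcripts on the lower side belonged to SOX11, OCIAD2, PAX7, SLC6A11 and LINC00665. SOX11 encodes a transcription factor of neural progenitors, and SOX11-201 (chromosome 2, 5692667 to 5701385) fell to 0.0026 from 3.35, with an adjusted p of 0.00110 in the authors' deposited table. OCIAD2 encodes a membrane protein of mitochondria and endosomes; OCIAD2-201 and OCIAD2-205 (chromosome 4, 48885019 to 48906937) were listed at 0 in the mutant group, against 4.2 and 3.06 in the parental one, and their adjusted p-values in the authors' deposited table were 0.0141 and 0.0469. PAX7 encodes a transcription factor of muscle stem cells and neural crest, and PAX7-203 (chromosome 1, 18631006 to 18748866) fell to 0.160 from 2.75, with an adjusted p of 0.0251 in the authors' deposited table. SLC6A11 encodes a transporter of the neurotransmitter GABA, and SLC6A11-201 was listed at 0 against 1.42. The long non-coding RNA LINC00665 fell as LINC00665-206, at 0.0111 against 2.61, and as LINC00665-207, listed at 0 against 0.573, while the whole gene stood at 0.0335 against 22.6. Minor transcripts of 3 widely expressed genes were lower too: USP14-207 (0.126 against 0.562), of a proteasome-bound deubiquitinase, ANKRD13C-203 (1.1e-06 against 0.271), of a receptor chaperone, and PRPF8-209 (2.2e-12 against 0.233), of a spliceosome core protein.

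On the higher side stood OR1C1 and TRBC2. OR1C1 encodes an olfactory receptor, and OR1C1-202 (chromosome 1, 247754846 to 247760556) reached 145 in the mutant group while listed at 0 in the parental one, with an adjusted p of 0.0435 in the authors' deposited table. TRBC2 encodes a constant region of the T-cell receptor beta chain, and TRBC2-201 (chromosome 7, 142801041 to 142802748) reached 11.3 against a listed 0, with an adjusted p of 0.0141 in the authors' deposited table. The other named higher transcripts had an abundance under 1. ZNF235-204, of a zinc finger repressor gene, stood at 0.735 against 2.1e-05, PABPN1-205, of a nuclear poly(A)-binding protein gene, at 0.361 against 1.8e-05, and NUCB2-212, of a calcium-binding protein gene, and FANCA-220, of a DNA crosslink repair gene, at 0.409 and 0.324 while listed at 0 in the parental group. Summed over all transcripts, ZNF235 had 1.69 against 1.76, NUCB2 67.7 against 39.3, PABPN1 130 against 106 and FANCA 34.5 against 32.2.

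At an adjusted p under 0.05 in the authors' deposited table, 31 transcripts differed, 19 of them higher (18 genes) and 12 lower (10 genes). An unadjusted p under 0.05 was held by 8135 transcripts (5.79%), 4645 higher and 3490 lower. With 1 transcript per gene, the most abundant, 3 genes were higher and 10 lower after a new adjustment over the 14856 genes, and 768 and 1282 had a p under 0.05. Abundance was under 1 in both groups for 17 of the 19 higher and 6 of the 12 lower transcripts. For 6 of the 19, among them BIRC6-AS2-201 and ACOXL-AS1-201, the values came down to 6 whole reads in total, 4 in 1 mutant library and 1 in each of the others, with none in the parental group.

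**Figure D2:**
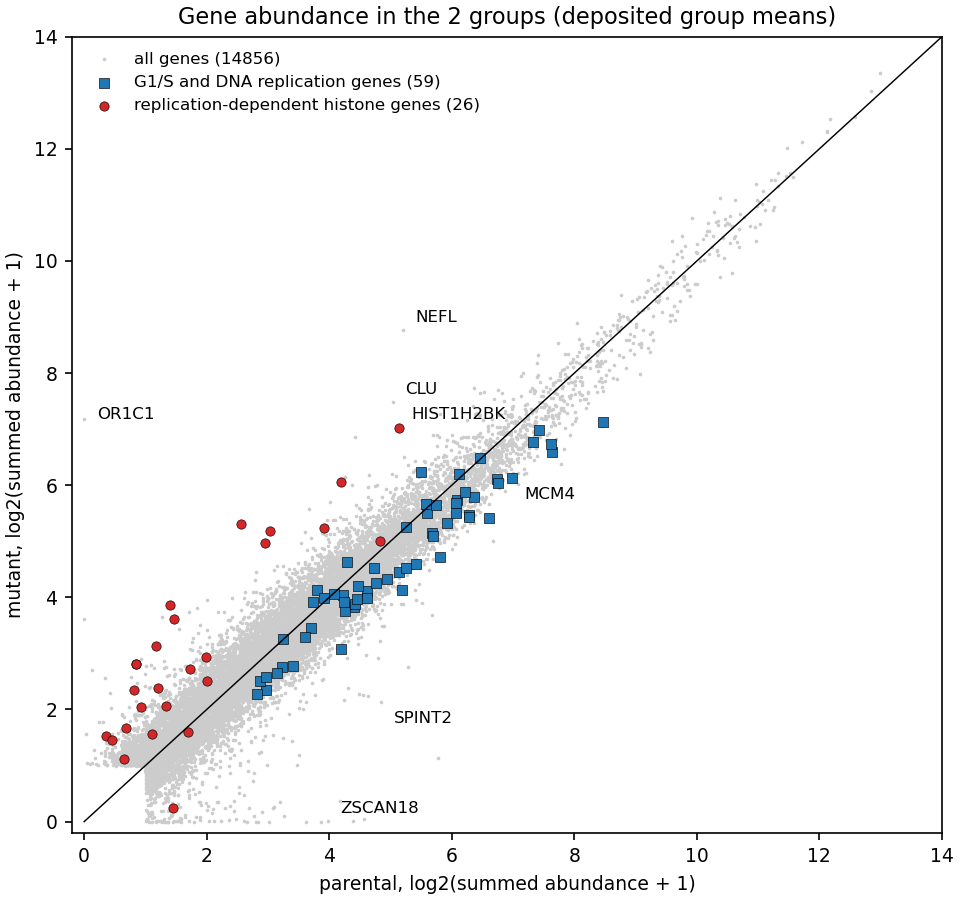
Abundance of each gene in the mutant and parental groups. CASP8AP2 lay at 15.7 and 15.9, and 3 genes were higher and 10 lower by their most abundant transcript.

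Replication-dependent histone genes rose as a group in the mutant libraries. Their typical messages end in a stem-loop in place of a poly(A) tail and peak in S phase. Gene sums do not tell these messages from longer forms of the same genes, and whether poly(A) RNA was selected was not given. HIST1H2BD (13.6 against 1.65), HIST1H4H (4.09 against 0.767), HIST1H2BK (130 against 34.3, on chromosome 6, 27146418 to 27146798) and HIST1H2AG (3.13 against 0.897) had the smallest p-values of the list. For the first it was 5.45e-05, held by HIST1H2BD-201 in the authors' deposited table. HIST1H1C, a linker histone gene, stood at 65.4 against 17.2. On the lower side lay HIST2H2AC, at 0.184 against 1.72, and HIST1H4J, at 2.02 against 2.25. Of 26 measured members 24 were higher and 2 lower, the median log2 ratio was 1.18 (quartiles 0.78 and 1.97), and the summed abundance was 455 against 138. The filter of at least 1 in either group kept some of these through the mutant group alone, and without it 60 members had a median of 0.37 (adjusted p 9.65e-09). The group differed from all other genes (cameraPR, p 4.01e-13, adjusted p 1.28e-11), and 95% of random lists of like abundance had a median between -0.18 and 0.20. No member was called over all genes, 17 higher and 1 lower had a p under 0.05, and adjusted over the list alone 6 were higher and 0 lower. Median GC content was 49.6%, and the median log2 ratio was 1.2 once the GC and length trends were taken out. Near-identical copies share reads, as with HIST2H3A and HIST2H3C (both 6.02 against 0.794) or HIST2H4A (38.7 against 4.87), so single members are uncertain. Such copies were counted as separate members. The p-value of the list may therefore be too small, and intervals over its genes too narrow.

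**Figure D3:**
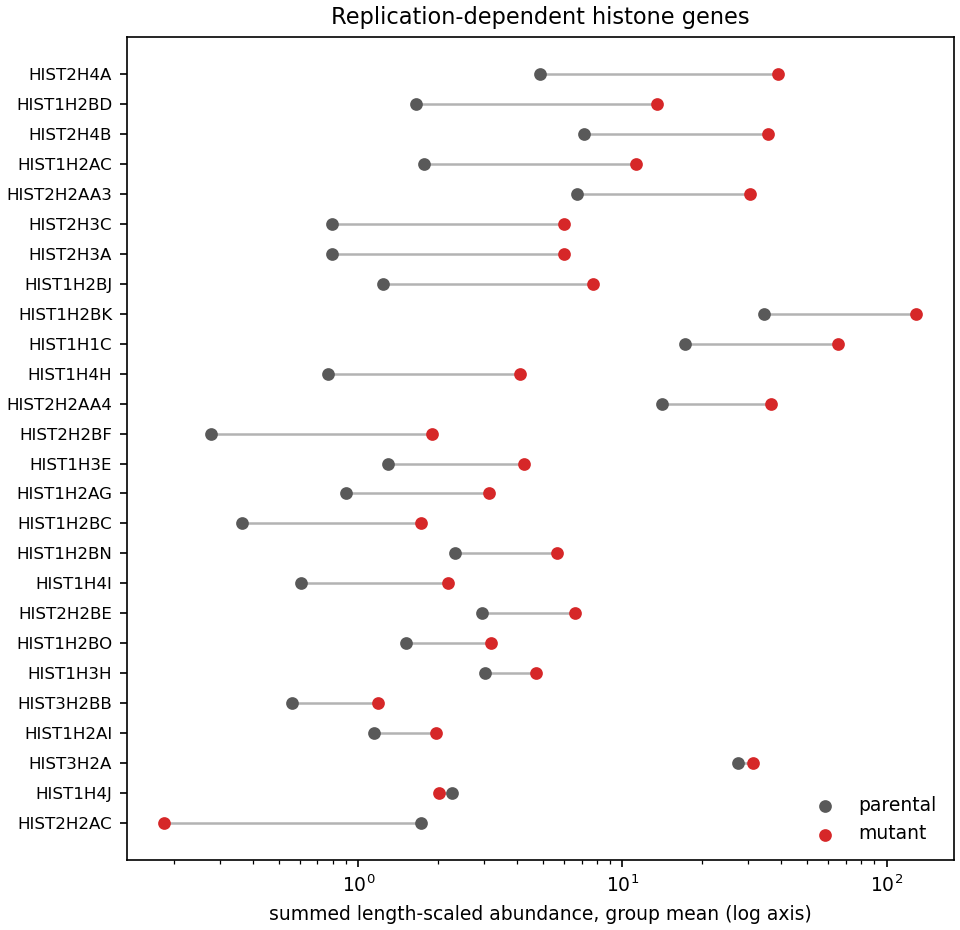
Abundance of the replication-dependent histone genes in the mutant and parental groups. Of 26 genes 24 were higher, with a median log2 ratio of 1.18.

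Histone genes that are expressed outside S phase, and carry poly(A) tails, were not shown to differ as a group. H2AFJ, an H2A variant gene, had 0.0352 against 4.59 and H3F3A, which encodes H3.3, 166 against 292, and both were lower when adjusted over this list alone. H3F3C (2.47 against 1.41) lay higher. The 12 measured genes had a median log2 ratio of -0.29, 4 higher and 8 lower (adjusted p 0.149, and 0.0438 without a filter on low values). Factors of histone message processing and the histone locus body, where CASP8AP2 acts, had a median of -0.17 over 18 genes, 6 higher and 12 lower (adjusted p 0.275), with CPSF3, the endonuclease of message 3' ends, at 20.7 against 28.9.

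Genes of G1/S and DNA replication, which E2F factors switch on as cells leave G1, fell as a group. CCNE2, the cyclin E2 gene, stood at 4.08 against 6.79 and was the single member lower when adjusted over the list alone. Its most abundant transcript, CCNE2-201, had a p of 0.000588 in the authors' deposited table. ATAD2, a chromatin ATPase gene, had 7.46 against 17.3, GINS2, of the replicative helicase, 21 against 34.3, DTL, of replication licensing control, 23.2 against 41.8, and MCM4, of the same helicase, 69.2 against 126. Of 59 measured genes 9 were higher and 50 lower, with a median log2 ratio of -0.50 (quartiles -0.63 and -0.22) and sums of 2141 against 3204. The difference from other genes was clear (cameraPR, p 1.86e-09, adjusted p 2.97e-08), and random lists gave medians between -0.18 and 0.07. No member was called over all genes, and 1 higher and 23 lower had a p under 0.05. With the GC and length trends taken out the median was -0.45.

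Genes of G2/M and mitosis were not shown to differ. LBR, an inner nuclear membrane protein gene, stood at 33.6 against 64.0, SMC4, of condensin, at 53.5 against 63.4, NUSAP1, of the spindle, at 45.6 against 57.1 and KIF20A, a cytokinesis kinesin gene, at 11.6 against 17.5. The median of 60 genes was -0.09, 24 higher and 36 lower (cameraPR, adjusted p 0.710), and no higher and 1 lower had a p under 0.05. Cyclins, cyclin-dependent kinases and the RB family had a median of -0.19 over 30 genes (adjusted p 0.107, and 0.0157 without a filter), and RBL1, which encodes the pocket protein p107, was lower when adjusted over the list alone (4.72 against 8.74, adjusted p 0.00839), as was CCNE2. CDK2 had 36.1 against 41.8 and E2F5 7.34 against 11.7. Inhibitors of these kinases and genes of quiescence had a median of 0.09 over 29 genes, 17 higher and 12 lower (adjusted p 0.128), with BTG1, an antiproliferative gene, at 37.2 against 23.9, DYRK1A at 11.7 against 9.72 and LIN9, of the DREAM complex, at 8.14 against 12.

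**Figure D4:**
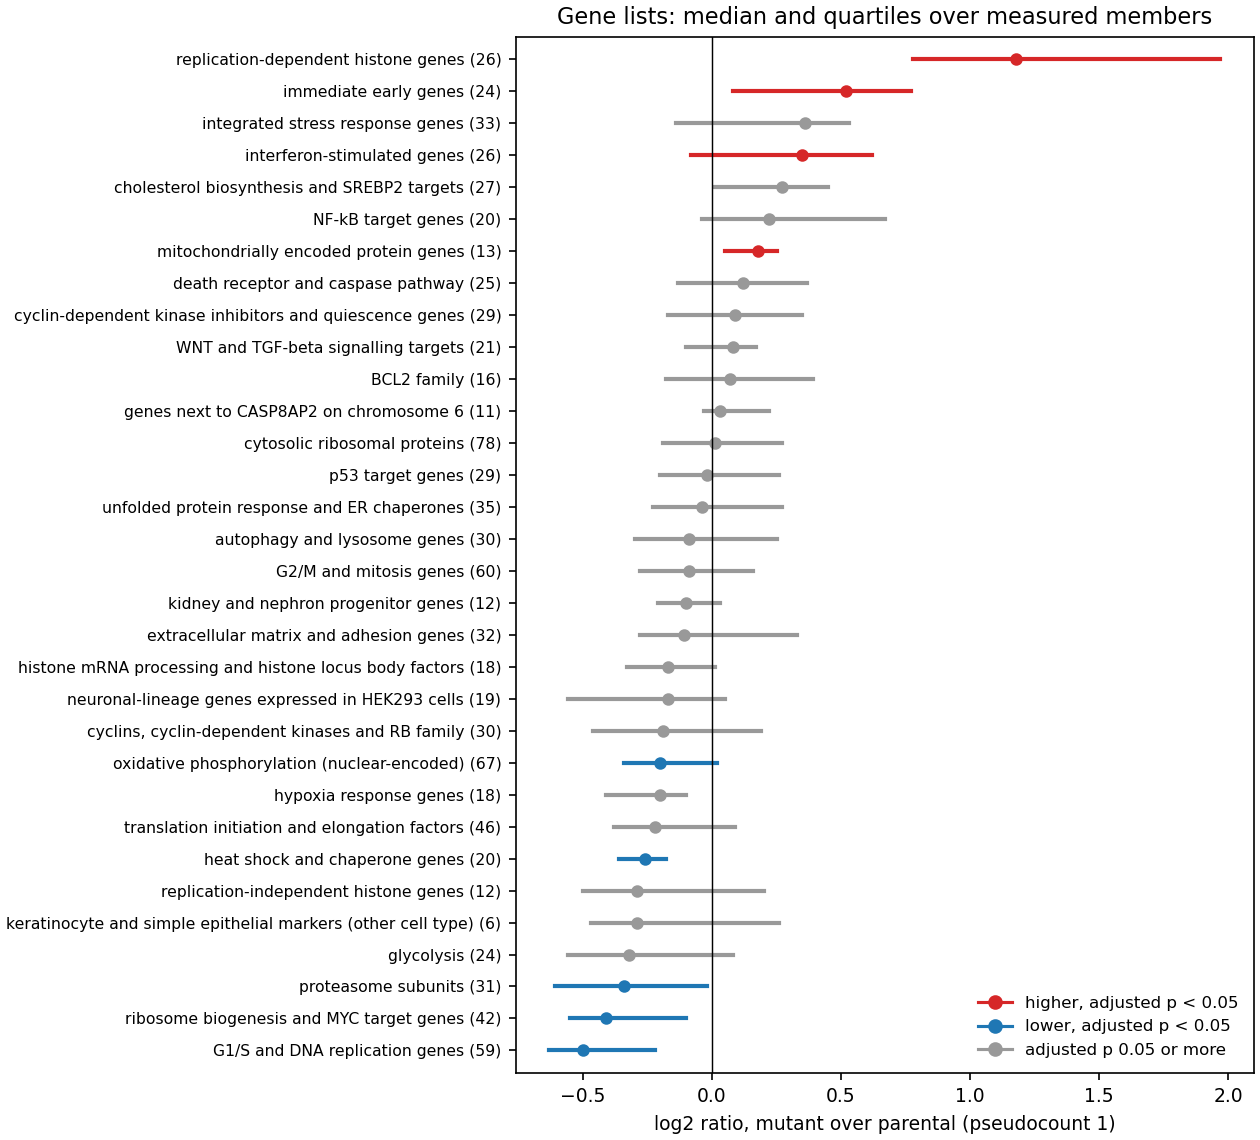
Median log2 ratio of each gene list with its quartiles. Replication-dependent histone genes had 1.18 and genes of G1/S and DNA replication -0.50.

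Proteasome genes, ribosome biogenesis genes and nuclear genes of oxidative phosphorylation, which together serve protein turnover, protein synthesis and respiration, were lower as groups in the main list test, and each call ended under at least 1 alternative. PSMC2 (31.1 against 54.0), PSMB2 (62.1 against 92.0) and PSMC4 (53.5 against 85.6) encode proteasome subunits and were lower when adjusted over their list alone, while a transcript of PSMD13 was higher there and its gene sum was 66.6 against 63.3. The 31 proteasome genes had a median of -0.34, 8 higher and 23 lower (cameraPR, adjusted p 7.99e-05), against -0.25 to 0.09 for random lists. At transcript level the median was -0.18 and the adjusted p 0.0635. Among ribosome biogenesis and MYC target genes stood NCL, of the nucleolus, at 157 against 256, MYBBP1A at 16 against 29.6, WDR12 at 18.1 against 27.4 and NOP58, of small nucleolar particles, at 39.3 against 81.5. The 42 genes of this list had a median of -0.41, 5 higher and 37 lower (adjusted p 0.00123, and 0.0693 at an inter-gene correlation of 0.05), against -0.20 to 0.09 for random lists, and -0.16 at transcript level. NDUFB3 (29.4 against 50.1) and NDUFB4 (63.4 against 91.7) encode subunits of complex I, COX6C (96.8 against 128) of complex IV and ATP5PB (100 against 153) of ATP synthase. The 67 respiratory genes had a median of -0.20, 18 higher and 49 lower (adjusted p 0.0146), inside the -0.22 to 0.02 of random lists. Their adjusted p was 0.232 at a correlation of 0.05, 0.0517 at transcript level and 0.0528 with the log2 ratio as the statistic.

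The 13 protein genes of mitochondrial DNA, which encode core respiratory subunits, lay the other way, with a median of 0.18, 11 higher and 2 lower (adjusted p 0.0354), against -0.38 to 0.16 for random lists. MT-ND3 stood at 2655 against 1998 and MT-CO1 at 10470 against 8105. Heat shock and chaperone genes had a median of -0.26 over 20 genes, 3 higher and 17 lower (adjusted p 0.0354), inside the -0.31 to 0.14 of random lists. HSPB1, a small heat shock protein gene, had 43.3 against 96.0, DNAJA1, an HSP40 co-chaperone gene, 49.5 against 86.8, HSPA6 0.625 against 1.05, and BAG3, of chaperone-assisted autophagy, 21.7 against 15.2. Neither call was firm: at an inter-gene correlation of 0.05 the adjusted p was 0.142 for the mitochondrial and 0.168 for the heat shock genes, with the log2 ratio as the statistic 0.454 and 0.0565, and at transcript level 0.0706 for the mitochondrial genes. Glycolysis genes had a median of -0.32 over 24 genes, 7 higher and 17 lower (adjusted p 0.107), outside the -0.25 to 0.14 of random lists. They were called at transcript level (0.0207), without a filter (0.0157), with GC and length trends taken out (0.0346) and with the log2 ratio as the statistic (0.0493). GAPDH (844 against 1326) and the glucose transporter gene SLC2A3 (3.42 against 10.4) were lower when adjusted over the list alone. Hypoxia response genes had a median of -0.20 over 18 genes (adjusted p 0.0884, and 0.0157 without a filter), with KDM3A, a histone demethylase gene, lower over the list alone at 7.39 against 12.5.

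Interferon-stimulated genes and immediate early genes were higher as groups in the main list test, and each call ended under at least 1 alternative. IFITM1, which encodes a membrane protein that blocks virus entry, was higher when adjusted over its list alone (14.9 against 6.55, adjusted p 0.0189). IFITM3, its relative, stood at 9.99 against 4.38, STAT2, of interferon signalling, at 14.8 against 9.0, and HLA-B, which presents peptides to T cells, at 16.5 against 41.4. The 26 interferon-stimulated genes had a median of 0.35, 16 higher and 10 lower (cameraPR, adjusted p 0.00405), against -0.20 to 0.18 for random lists. The adjusted p was 0.0693 at a correlation of 0.05, and 0.0988 at transcript level with a median of 0.18. JUN (255 against 142) and FOS (321 against 170), subunits of the AP-1 transcription factor, and KLF6 (19.6 against 11.7) lay higher, and IER3, of NF-kB feedback, lower at 7.16 against 12.6. The 24 immediate early genes had a median of 0.52, 18 higher and 6 lower (adjusted p 0.0146), against -0.23 to 0.15 for random lists. With the GC and length trends taken out the call ended (adjusted p 0.121) while the median stayed at 0.47, and at a correlation of 0.05 the adjusted p was 0.137.

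Death receptor and caspase genes, the pathway for which CASP8AP2 was named, were not shown to differ. RIPK1, a kinase at the receptor complex, stood at 11.1 against 8.05, TRAF2, an adaptor, at 10.7 against 7.0, FADD, the adaptor of caspase 8, at 17.2 against 10.2 and CYCS, which encodes cytochrome c, at 91.1 against 151. The median of 25 genes was 0.12 (cameraPR, adjusted p 0.280). In the BCL2 family, which gates cell death at mitochondria, the median of 16 genes was 0.07 (adjusted p 0.318), and BNIP3L, a receptor of mitophagy, was lower over the list alone at 9.88 against 21.2. Targets of p53, which halts damaged cells, had a median of -0.02 over 29 genes (adjusted p 0.866), with RRM2B at 6.05 against 10.3, TIGAR at 2.55 against 3.89, TRIAP1 at 36.1 against 39.9 and TP53I3 at 1.05 against 1.07. NF-kB targets had a median of 0.22 over 20 genes (adjusted p 0.0883, 0.0207 at transcript level and 0.0108 with the log2 ratio as the statistic), with the chemokine gene CCL20 at 2.43 against 0.243.

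Groups that serve protein making, lipid synthesis and lysosomes were not called in the main list test, though some were under alternatives. CALR, a chaperone gene of the endoplasmic reticulum, stood at 143 against 185, SYVN1, a ligase of protein quality control, at 22.6 against 15, and DERL2 and DERL1, of the same degradation route, at 14.3 against 24.5 and 15 against 18.1. Those 35 genes of the unfolded protein response had a median of -0.04 (cameraPR, adjusted p 0.661). Integrated stress response genes had a median of 0.36 over 33 genes, 21 higher and 12 lower (adjusted p 0.136), outside the -0.25 to 0.08 of random lists. PHGDH, of serine synthesis, stood at 295 against 363 and ATF4, the transcription factor of this response, at 1018 against 781. They were called at transcript level (adjusted p 0.00308) and with the log2 ratio as the statistic (0.0258). Cytosolic ribosomal proteins had a median of 0.01 over 78 genes (adjusted p 0.153), and RPS3 stood at 2165 against 1573. Translation factors had a median of -0.22 over 46 genes (adjusted p 0.131, and 0.0157 without a filter), with EIF1AX, of start codon choice, at 14.5 against 41.6. Cholesterol synthesis genes had a median of 0.27 over 27 genes, 21 higher and 6 lower (adjusted p 0.280), outside the -0.23 to 0.15 of random lists, and were called at transcript level (0.0338) and with the log2 ratio as the statistic (0.0419). Autophagy and lysosome genes had a median of -0.09 over 30 genes (adjusted p 0.902), with CTSB, a lysosomal protease gene, at 65.2 against 40.

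Genes of cell identity were mixed. GAP43, of growing axons, was lower when adjusted over the neuronal list alone (0.986 against 2.23). The median of 19 neuronal genes that HEK293 cells express was -0.17 (cameraPR, adjusted p 0.171, and 0.0347 without a filter). FOXD1, of kidney stroma, had 18.6 against 25.4 and PAX2, of nephron progenitors, 3.08 against 1.80, in 12 kidney genes with a median of -0.10 (adjusted p 0.661). Extracellular matrix genes had a median of -0.11 over 32 genes (adjusted p 0.707), with the collagen gene COL6A1 at 45.9 against 21.9 and MMP2, a matrix protease gene, at 1.45 against 4.30. Targets of WNT and TGF-beta had a median of 0.08 over 21 genes (adjusted p 0.707), with ID1 at 20.5 against 29.

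Markers of other cell types were few. LCP1, which encodes an actin-bundling protein of white blood cells, stood at 0.289 against 17.1, and CORO1A, another leukocyte actin regulator, at 3.38 against 1.86. Fibroblast markers were present as COL1A1 (5.82 against 2.17), S100A4 (0.372 against 1.27), LUM (1.06 against 1.49) and ACTA2 (26.1 against 35.3). At an abundance of at least 1 the 2 leukocyte and 4 fibroblast markers were too few to test, and 0 erythroid or liver markers were measured. Without a filter 10 leukocyte, 11 fibroblast and 8 erythroid or liver markers were not called (adjusted p 0.564, 0.797 and 0.754). Epithelial keratin markers, some of which HEK293 cells express, had a median of -0.29 over 6 genes (cameraPR, adjusted p 0.147, and 0.0499 at transcript level), with KRT8 at 37.3 against 70.5 and EPCAM, of cell adhesion, at 1.16 against 2.02. No cell types were assigned, since the libraries came from a single line.

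Over the 32 lists with at least 5 measured genes, 9 had an adjusted p under 0.05, and in no list was a member called over all genes. At an inter-gene correlation of 0.05, 3 lists remained: replication-dependent histone genes (adjusted p 2.0e-06), genes of G1/S and DNA replication (0.00205) and proteasome subunits (0.0131). Only the first 2 of these were called under all 7 alternatives, since the proteasome call ended at transcript level, and 19 lists were called under at least 1 setting. The alternative with an added 0.1 kept the same statistic in the list test, so it could not change a call. An estimated correlation could not be had from group means.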

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

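Tests of GC and length trends, of an inter-gene correlation of 0.05, of the log2 ratio as statistic, of the p-value for the factor Type and of calls without the transcripts of 6 reads were chosen after the results were seen, and the cause of each change below was not tested. The 19 higher transcripts became 2 at an abundance of at least 1, 2 at 5, 0 at an adjusted p under 0.01, 2 with an absolute log2 ratio of at least 1, 3 at gene level, 9 with the p-value for the factor Type and 13 without the transcripts of 6 reads; the 12 lower became 6, 0, 1 and 6 under the first 4 of these alternatives. CASP8AP2 had a log2 ratio of 0.08 with trends removed, and ZNF235 had -0.03 at gene level. The 9 called lists became 3 at a correlation of 0.05 and 15 without a filter. An added 0.1 changed the medians of lists but not the statistic tested, so their calls could not change under it. Replication-dependent histone genes kept a median between 0.37 and 1.96 under 7 alternatives (highest adjusted p 2.0e-06), genes of G1/S between -0.54 and -0.39 (0.00205), and G2/M genes stayed without a call (lowest 0.348). Only the first 2 of these were called under every alternative; at transcript level the calls ended for proteasome (adjusted p 0.0635), interferon-stimulated (0.0988), respiratory (0.0517) and mitochondrially encoded genes (0.0706) and came up for integrated stress response (0.00308), glycolysis and NF-kB (each 0.0207), cholesterol (0.0338) and keratin genes (0.0499). Medians of lists without a call changed sign: kinase inhibitors -0.00 and BCL2 family -0.02 at an abundance of at least 5, BCL2 family -0.00 and keratins 0.00 without a filter, p53 targets 0.06, ER chaperones 0.12, matrix genes 0.05 and autophagy genes 0.10 at transcript level, ER chaperones 0.02 and WNT and TGF-beta targets -0.01 with trends removed, and the latter -0.03 at 5. No paired analysis was possible because the values given for the comparison were group means, and for the same reason no library could be left out and no other normalization or test tool could be run.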

Other observations

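The tests of summed histone abundance, S phase genes, cell cycle genes as a whole, copies of chromosome 19 and zinc finger genes on other chromosomes were chosen after the result was seen; the other tests were written down beforehand, with the untreated medians already known.

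Large differences, picked after the values were seen, included genes of several kinds beside the histone and zinc finger genes. OR2B4P, an olfactory receptor pseudogene, had 0.00676 against 20. NEFL, the light neurofilament gene, stood at 434 in the mutant group against 35.7, while its neighbour NEFM had 0.069 against 8.63 and INA, of a related filament, was listed at 0 against 6.11. CLU, which encodes the extracellular chaperone clusterin, had 177 against 31.9, and CLU-202 had a p of 0.000321 in the authors' deposited table. RNF122, a ubiquitin ligase gene, stood at 115 against 20.4 and CXCL8, a chemokine gene, at 13.2 against 1.73. PURPL, a p53-linked RNA, had 13 against 2.57 and BCHE, which encodes butyrylcholinesterase, 6.49 against 0.898. On the lower side MYADM, of membrane rafts, was listed at 0 against 13.5, OXCT1, of ketone body use, had 0.279 against 8.18, CTSZ, a lysosomal protease gene, 0.195 against 7.56, SPINT2, a protease inhibitor gene, 3.38 against 27.7, and BEX1, of neurotrophin signalling, 0.177 against 5.42. None of these genes was called over all genes.

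Zinc finger genes on chromosome 19 included a large share with far lower values in the mutant group. Many such genes encode KRAB repressors of transposable elements. None of the low ones was called in the authors' deposited table. With 1 transcript per gene, the most abundant, ZNF569 was among the 10 genes lower after the new adjustment over 14856 genes. ZNF569 stood at 0.0763 against 5.8, and ZNF569-201 had a p of 3.87e-05 in the authors' deposited table. ZNF829 stood at 0.000943 against 5.3, ZNF568, an embryonic repressor gene, at 0.0106 against 5.1 and ZNF331, an imprinted gene, at 3.76 against 22.5. ZNF738 was listed at 0 against 5.95. ZSCAN18, of the SCAN family, had 0.00386 against 14.8. Of 108 such genes with an abundance of at least 3, 21 had a log2 ratio below -1 and 1 above 1, and the adjusted p-values of the 21 lay between 0.0922 and 0.703 in the authors' deposited table. Of the 614 other genes on chromosome 19, 9 lay below -1 (Fisher's exact test, p 3.6e-12, with the genes and the threshold chosen after the values were seen), and of 181 zinc finger genes elsewhere 1 did. That test took genes as independent units. Some of the low genes were close neighbours that may change together, so its p-value may be too small.

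The gain in replication-dependent histone genes may come from messages that escape normal 3' end processing and degradation if CASP8AP2 function was lost, though no fall of its RNA was seen (log2 ratio -0.01) and its protein was not analysed here. Reads moving between near-identical copies would leave the sum level, yet it rose by a ratio of 3.3 (interval 2.34 to 4.34), and the median stayed at 1.2 (0.99 to 1.78) without GC and length trends. Genes of G1/S had a median of -0.5 (-0.58 to -0.38), which argues against more cells entering S phase. These genes are switched on as cells leave G1, so they cannot tell whether cells stayed longer in S phase. More RNA without a poly(A) tail in the mutant libraries should raise stable RNAs of that kind too. The 11 measured ones, such as RN7SK and RMRP, had a median of 0.23 (-0.04 to 0.56), below the 0.6 written beforehand. That 0.6 was set from the histone median already known. Of 34 listed RNAs only these 11 were measured, 7 higher and 4 lower. Some had low values, such as RNU2-2P (1.22 against 0.385) and SCARNA12 (0.9 against 1.33). A smaller gain of RNA without a poly(A) tail is therefore left open. In 7 of 9 genes with several forms the longest had a higher log2 ratio than the shortest (sign test, p 0.18), which leaves read-through open. The near-identical HIST2H4A and HIST2H4B were counted apart in this test. Read coverage past the stem-loops, not used here, would separate message gain from extension. Any other difference between the mutant and parental cells is confounded with the edit. Independent mutant lines would be needed to link the gain to CASP8AP2.

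The fall in genes of G1/S and DNA replication is consistent with fewer cells entering S phase, but an arrest at G0/G1 should also leave fewer cells in G2/M, whose genes were not shown to fall (median -0.09, adjusted p 0.710), and quiescence genes were not shown to rise (0.09, adjusted p 0.128). GC and length trends left a median of -0.45 (-0.51 to -0.32). The median of G2/M genes lay 0.41 above that of G1/S (two-sided permutation p 2.0e-05, the smallest that 100000 draws can give with both sides counted), which argues against an equal fall of all cell cycle genes, with genes in place of cultures as units. A slower growth state is not ruled out: ribosome biogenesis and MYC target genes were lower too without the trends (median -0.37, adjusted p 0.00019), though that list was not called at an inter-gene correlation of 0.05 (adjusted p 0.0693) and had a median of -0.16 at transcript level. Cell counts by DNA content at matched density would tell these apart. Such counts could not tell an effect of the edit from another difference between the mutant and parental cells, which this design leaves confounded.

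The low values of zinc finger genes on chromosome 19 could be silencing fixed in the cells from which the mutant line grew, since edited lines often pass through few cells, and whether this was so here was not given in the sources used here. Loss of whole copies of chromosome 19 is unlikely, with a median of 0.02 (-0.01 to 0.06) over its other 614 genes. That median cannot show the loss of short stretches, which was not tested. Some of the low genes were close neighbours, such as ZNF345, ZNF829 and ZNF568 between 36850361 and 36998700. GC and length trends left 21 of 21 genes below -1. Low depth in the mutant libraries would lower zinc finger genes of this abundance elsewhere too, where 1 of 181 lay below -1. The depths argue against it as well. They were an estimated 57440000, 15000000 and 13280000 reads in the mutant libraries, against 15290000, 11590000 and 9180000 in the parental ones. All 21 genes had at least 20 reads expected in the mutant libraries (median 1677), but the choice of abundant genes had fixed that outcome. An effect of CASP8AP2 itself remains open, and independent mutant lines would separate it from chance differences between lines.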
